A study of Mus musculus with 5 samples.

How the data were processed

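RNA from asynchronous mouse ES cells was measured on Affymetrix whole-transcript expression arrays, 1 array for each of 3 wild-type and 2 Dicer-deficient cultures. Per the labels' protocols, biotin-labelled cRNA was prepared from total RNA extracted with a phenol-based reagent. The authors deposited 1 table with a normalized log2 signal for each of 35556 probe sets on each array, rounded to 2 decimals. How the authors corrected the background, summarised probes and normalized the arrays is not given in the sources used here, nor is the log base. The values were read as log2 signals, already normalized, because all are positive, span about the range of 16-bit scanner intensities on that scale, and have array medians of 5.39 to 5.45. A different base would rescale every change given as a log2 or fold value but no p-value. Arrays were assigned to groups by their titles, and no value column was without a sample.

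Probe sets were named through the platform's annotation, which can be old: 21789 had 1 gene symbol, 1621 several and 12146 none. Probe sets with several symbols or none were named nowhere. Of the genes so named, 19856 of 19939 were found by gene identifier in a gene table of the GRCm38.p6 assembly. It updated 0 symbols and gave 19853 genes a chromosome and a place in gene order. No coordinates are given because the array annotation names no build. For 998 genes with several probe sets, the probe set with the highest mean over the 5 arrays was used.

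The main test was chosen before the data were examined, as were the gene lists, the alternatives and the rule for named genes. It was limma's linear model with empirical Bayes moderation (lmFit and eBayes) on the deposited values, Dicer-deficient minus wild type, with no covariate, and Benjamini-Hochberg adjustment over 19939 genes at 0.05. The fit had 3 residual and 4.55 prior degrees of freedom. An exact permutation of 3 against 2 arrays has 10 splits and cannot go below a two-sided p of 0.1, so no permutation p is given. SDs are between arrays, and SEs are limma's moderated ones. The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

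Gene lists with at least 5 measured members, 37 in all, were tested with camera at a preset correlation of 0.01, two-sided, and Benjamini-Hochberg adjusted over the lists. With an estimated correlation camera works on the 3 residual degrees of freedom, and 0 of the 14 calls held. The counts "adjusted over the list alone" come from adjusting the genes' p-values within a list. Chromosomes were tested in the same way over the genes whose mean level lay above the median of all probe sets, 5.41. One name in the list of microRNA host transcripts resolved to Mprip, which is not such a host and had a change of 0.05. The planned comparison of genes with and without microRNA seed matches in their 3′ UTRs was not run, since no transcript sequences were used here.

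The genes named are the 15 largest rises and 15 largest falls among called genes whose Dicer-deficient values both lay outside the wild-type range, passing over provisional names. To these come up to 4 of the largest called changes in each list and a fixed set of genes of the microRNA pathway, pluripotency and cell cycle. These rules gave 162 genes, of which 151 were called and 90 kept their call when each array was left out in turn; the text names a part of them. Genes named outside the rules, to spell out a count of 5 or fewer, in the closing section or as ends of a chromosome run, were chosen after their values were seen. Those named only to spell out a count were followed through leaving out each array and not through the other alternatives. A rise or fall by an amount is a log2 change unless given as a fold. Signal over background was not analysed here, so a change to or from a signal below the median of all probe sets has an uncertain size. Cdkn1a and Trp53 were in the fixed set and are not reported here, because no probe set carried either symbol alone.

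Alternatives were another quantile normalization, median centring, leaving out dim genes, an intensity trend, robust moderation, array weights, the replicate number as a block, and leaving out each array. Further ones were the mean of a gene's probe sets, all probe sets, a minimum change of 2-fold, and limma's treat against 1.2-fold. List tests were repeated with fry, with ranks and with an estimated correlation. Added after seeing the data were 10000 random lists matched on mean level and gene span, a fit without genes of chromosomes 14 and Y, and 3 further lists. Windows of 25 neighbouring genes were used to place chromosome shifts, and were formed again from every other gene so that the genes left out could be read separately.

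The fit and the list test were tested on simulated values for the 19939 genes. These had the wild-type means and spreads drawn from the fitted prior, and each gene varied independently of the others. The fit recovered 20 of 67 genes changed by 0.5 on the log2 scale (29.9%), 64 of 67 changed by 1 (95.5%) and 65 of 66 changed by 2 (98.5%), with 6 false calls among 155. The list test called 40 of 40 shifted lists and 3 of 40 unchanged ones. In the test of the fit far fewer genes were changed than the 3404 called in the data, so its recovery shares need not carry over. Members of the real lists can vary together, with an estimated correlation of up to 0.638, and the list result does not cover such lists. No array pair had nearly identical values: at most 5.45% of probe sets had the same value on any pair.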

Results

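Gene expression was measured in mouse embryonic stem (ES) cells, pluripotent cells from the early embryo, that were either wild type or deficient in Dicer. Dicer is the ribonuclease that cuts microRNA precursors into mature microRNAs. Both kinds of cell were grown without feeder cells in a mixture of serum and LIF medium with a serum-free medium holding 2 kinase inhibitors, and were collected from asynchronous cultures. There were 3 wild-type and 2 Dicer-deficient arrays, which the series' design text describes as biological replicates. The early G1 samples that the design text also describes, and a further Dicer-deficient culture, were not analysed here. Each array gave a log2 signal for 35556 probe sets, from which 19939 genes with a name of their own were tested. The 5 array medians lay between 5.39 and 5.45, and the number of arrays limits the precision of every value given here. The array titles give the genotype and a number but no cell line. Effects of Dicer loss therefore cannot be told apart from other differences between the wild-type and the Dicer-deficient cells.

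The question the design poses is how the transcripts of ES cells differ when Dicer is missing. Dicer1 itself, on chromosome 12, was the first gene examined. Its signal was 8.84 ± 0.0153 (SD, n = 3) in wild-type cells and 7.02 ± 0.255 (SD, n = 2) in Dicer-deficient cells. The log2 change was -1.82 with a standard error (SE) of 0.112, a level 3.52-fold lower (adjusted p = 0.000129). Which part of the gene was deleted is not given in the sources used here, so the signal checks the labels only as far as the probe set reads the deleted part.

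Anxa3 and Casq2 rose most in Dicer-deficient cells, and Obox6 and Lin28a fell most. Lin28a, an RNA-binding protein that blocks the maturation of let-7 microRNAs, went from 8.87 ± 0.0643 (SD, n = 3) to 5.84 ± 0.0849 (SD, n = 2), an 8.15-fold lower level (log2 change -3.03, SE 0.0836, adjusted p = 6.08e-06). Anxa3, a calcium-dependent phospholipid-binding annexin, rose from 5.34 ± 0.238 to 9.54 ± 0.0778 (log2 change 4.20, SE 0.136, adjusted p = 6.34e-06). Casq2, the calcium-storing calsequestrin of heart muscle, rose from 4.48 ± 0.0656 to 8.13 ± 0.0778. Both wild-type signals lie below the median of all probe sets, 5.41, and were not shown to be above background, so no fold is given. Obox6, of an oocyte-specific homeobox family, fell (log2 change -3.14, SE 0.203, adjusted p = 0.000145) to a signal of 3.47, below the lower quartile of every array, 4.14 to 4.18, so the size of the fall rests on a signal not shown to be above background.

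The other genes among the 15 largest rises were Crybg3, Parva, Tmem64, Cd3g, Dpp4, Egfl6, Msln, Smyd1, Slc40a1, Tbc1d8b, Ido2, Ptgr1 and Gpx2, with log2 changes from 2.65 to 3.11. Parva links integrins to actin, Dpp4 is a cell-surface peptidase, Slc40a1 is the iron exporter ferroportin and Smyd1 is a histone methyltransferase of muscle. Gpx2 is a glutathione peroxidase, and Cd3g belongs to the T cell receptor complex. The largest falls after Obox6 and Lin28a were those of Pla2g1b, Upp1, Rpl39l, Bex4, Rragb, Ddit4, A2m, Usp26, Elobl, Kdelr3, Phlda2, Bex1 and Ly6e. Their log2 changes lay between -2.85 and -2.02. Pla2g1b is a secreted phospholipase, which fell from 10.94 ± 0.0666 to 8.09 ± 0.0212. Rragb is a GTPase of amino acid sensing, and Ddit4 restrains mTOR signalling. Of these 30 genes, 27 kept their call when each array was left out in turn. Usp26 had adjusted p = 0.0727 without Dicer-deficient array 1 and 0.0857 without array 2, Rpl39l had 0.0579 and 0.0576, and Ddit4 had 0.0509 without Dicer-deficient array 1. The Dicer-deficient signal of Usp26 also lay below the arrays' lower quartiles. The wild-type signals of Crybg3, Parva, Egfl6, Smyd1, Slc40a1 and Tbc1d8b, from 4.24 to 5.27, lay below the median of all probe sets. So did the Dicer-deficient signals of Rpl39l, Rragb, A2m and Kdelr3, from 4.17 to 5.205. None of these signals was shown to be above background, so the sizes of these changes are uncertain.

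**Figure D1:**
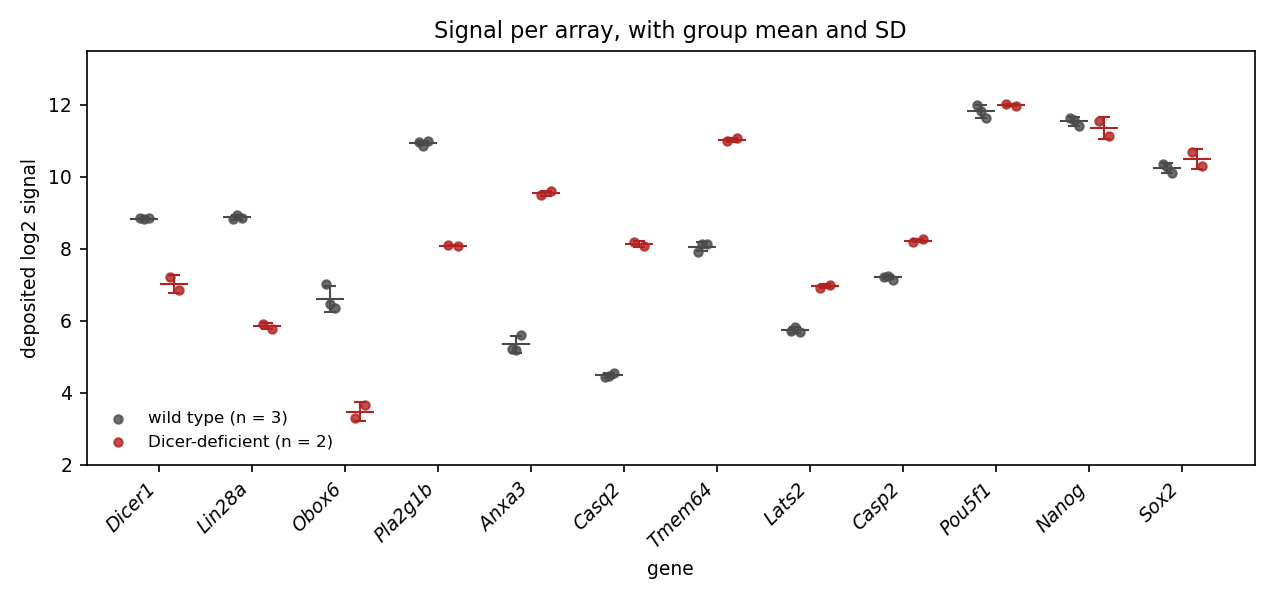
Deposited log2 signal (vertical axis) of 12 genes on each array, with wild-type arrays in grey (n = 3), Dicer-deficient arrays in red (n = 2), and group means with SD as horizontal bars and whiskers. Dicer1, Lin28a, Obox6 and Pla2g1b sat lower and Anxa3, Casq2, Tmem64, Lats2 and Casp2 higher in the Dicer-deficient cells, whereas the group means of Pou5f1, Nanog and Sox2 lay within 0.26 of each other.

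Across all genes, 3404 of 19939 passed an adjusted p of 0.05 in limma, 1690 higher and 1714 lower in Dicer-deficient cells. Both Dicer-deficient values lay on the same side of the wild-type range for every one of the 3404, which the call itself largely entails. Over all genes tested 39.9% showed this separation, which chance gives for 20% of genes. A change of at least 2-fold was seen for 307 of the genes called higher and 151 of those called lower. The first principal component, with 74.3% of the variance, separated the genotypes. The number of calls fell whichever array was left out, with fewer arrays to estimate the spread. It was 1180 higher and 1000 lower without wild-type array 1, 972 and 769 without array 2, and 1396 and 1560 without array 3. The number fell furthest without either Dicer-deficient array, which leaves 1 array in that group.

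Genes reported as targets of the miR-290, miR-302 and miR-17 families, abundant microRNAs of mouse ES cells, tended to be higher. Of 31 measured, 11 rose, 2 fell and 18 did not pass the test (13 and 3 adjusted over the list alone), with a median log2 change of 0.18. The list stood above other genes in camera (adjusted p = 2e-04; adjusted p = 0.449 with an estimated correlation). Lats2, a Hippo pathway kinase, rose 2.33-fold from 5.73 ± 0.085 (SD, n = 3) to 6.96 ± 0.0495 (SD, n = 2), and Casp2, a caspase, rose 2.03-fold. Mbd2, which binds methylated DNA, rose 2.39-fold, Dazap2 2.60-fold and the pro-apoptotic Bcl2l11 2.50-fold. The pocket protein gene Rbl2 rose 1.77-fold (adjusted p = 0.00445), with adjusted p = 0.104 and 0.0571 without Dicer-deficient array 1 and array 2. The Nodal antagonists moved apart: Lefty2 fell (log2 change -1.26, adjusted p = 0.0019), while Lefty1 rose by 0.96 on the log2 scale, a call lost when each wild-type array in turn (adjusted p from 0.073 to 0.107) or Dicer-deficient array 1 (0.106, with a log2 change of 0.57) was left out. Slain1 was the other reported target that fell. Slain1 lost its call without Dicer-deficient array 1 or 2 (adjusted p from 0.0524 to 0.0558).

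Among 22 reported let-7 targets, 7 rose and 5 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.856), and Igf2bp3, an RNA-binding protein, was 1.99-fold lower, besides Lin28a, Dicer1, Nras and Trim71. Of 29 genes of the small RNA machinery, 5 rose and 4 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.856). The median of that list, -0.02, turned to 0.01 when the arrays were quantile normalized again, and to 0.03 without wild-type array 1 or Dicer-deficient array 2. Besides Dicer1 and Lin28a, the called members included Mov10, an RNA helicase, with a log2 change of 0.98, and the Argonaute partner Tnrc6a with 1.19 (adjusted p = 0.0517 without Dicer-deficient array 2). The others were Ago1, Tnrc6b and Lin28b, which rose, and Trim71 and Adar, which fell. The nuclear processing genes Drosha and Dgcr8 had changes of -0.01 and 0.01 (adjusted p = 0.978 and 0.955), which ran from -0.07 to 0.05 and from -0.05 to 0.07 as each array was left out, and Ago2 had -0.27 (adjusted p = 0.0515). Of 300 probe sets for microRNA genes, 8 were called higher and 0 lower by limma (5 and 0 adjusted over the list alone; camera adjusted p = 0.843). The largest were from the miR-302 cluster, with log2 changes of 1.79 for Mir302c, 1.77 for Mir302d and 0.96 for Mir302a. Mir302b rose by 1.91, with adjusted p = 0.0523 and 0.0634 without Dicer-deficient array 1 and array 2. Their wild-type signals, 3.42 to 4.03, lay below the lower quartile of every array, 4.14 to 4.18, so the sizes of these rises rest on signals not shown to be above background, and the platform does not separate precursor from mature forms. Adar and Trim71 lost their call without wild-type array 1 or 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.121 to 0.292). Nras and Tnrc6b lost their call without Dicer-deficient array 1 (adjusted p from 0.0503 to 0.0602). Ago1 and Lin28b lost their call without Dicer-deficient array 1 or 2 (adjusted p from 0.0509 to 0.157).

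The core pluripotency transcripts did not pass the test. Pou5f1 changed from 11.82 ± 0.18 (SD, n = 3) to 11.99 ± 0.0283 (SD, n = 2), with adjusted p = 0.404 and a change of 0.08 without wild-type array 3 and 0.26 without wild-type array 1. The changes of Nanog and Sox2 were -0.20 and 0.26 (adjusted p = 0.446 and 0.279). Nanog had -0.41 without Dicer-deficient array 1 and 0.02 without array 2, and Sox2 had 0.06 and 0.45. Of 35 naive pluripotency genes, 5 rose, 8 fell and 22 did not pass (5 and 9 adjusted over the list alone; camera adjusted p = 0.214, and 0.0477 without wild-type array 3). Tcl1, a coactivator of Akt, fell by 1.60 on the log2 scale (adjusted p = 0.00124, and 0.0559 without Dicer-deficient array 2). The naive transcription factors Tbx3 and Klf4 fell by 1.18 and 0.95. For Tbx3 the adjusted p was 0.0506 without wild-type array 2, 0.0861 without Dicer-deficient array 1 and 0.144 without array 2. For Klf4 it lay between 0.0504 and 0.0914 without each wild-type array and was 0.101 without Dicer-deficient array 2, with a log2 change of -0.59. Manba rose 2.08-fold, and the others called higher were Klf2, Pecam1, Gdf3 and Dppa2. Of 21 primed epiblast genes, 8 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.133), among them the kinase Pim2, with a log2 change of 0.71; Cldn6 was the member that fell. Cldn6 lost its call without wild-type array 1 or 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.0507 to 0.244). Dppa2 lost its call without wild-type array 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.106 to 0.184). Klf2 lost its call without Dicer-deficient array 1 (adjusted p = 0.0558). Gdf3 lost its call without Dicer-deficient array 1 or 2 (adjusted p from 0.064 to 0.0857).

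Of the lineage lists, trophectoderm alone passed the camera test: 6 of 20 rose and 0 fell in limma (7 and 2 adjusted over the list alone; camera adjusted p = 0.037; adjusted p = 0.661 with an estimated correlation). These included the keratin Krt8, which rose 2.90-fold, and the transcription factor Gata3, which rose 2.35-fold. The list's call was lost without wild-type array 1 (adjusted p = 0.0902), wild-type array 2 (0.053), Dicer-deficient array 1 (0.0957) or Dicer-deficient array 2 (0.0528). Its median log2 change was 0.06, but 0.04 without wild-type array 1, 0.12 without wild-type array 3 and 0.145 without Dicer-deficient array 2, and the wild-type arrays themselves had median deviations of -0.07, 0.00 and 0.11 over it. Primitive endoderm markers had 2 higher and 2 lower of 25 (2 and 2 adjusted over the list alone), with the laminin chain Lamb1 at a log2 change of -1.42 (camera adjusted p = 0.843); the others called were Lama1, Lrp2 and Srgn. Mesoderm and primitive streak markers had 5 higher and 0 lower of 26 (5 and 0 adjusted over the list alone; camera adjusted p = 0.41), namely Kdr, Msx2, Gsc, Evx1 and Snai1. Neuroectoderm markers had 3 higher and 3 lower of 30 (3 and 3 adjusted over the list alone; camera adjusted p = 0.859), with Pax6 higher by 0.96, Olig1 at -0.85, Cdh2 and Map2 also higher, and Msi1 and Olig2 also lower. None of 37 Hox genes was called by limma (0 and 0 adjusted over the list alone; camera adjusted p = 0.65). Feeder fibroblast markers had 0 higher and 2 lower of 26 (0 and 1 adjusted over the list alone; camera adjusted p = 0.593). The called members were the imprinted noncoding RNA Meg3 and Igfbp4, the latter with adjusted p = 0.0318. Its call was lost without wild-type array 2 (0.132), wild-type array 3 (0.0843), Dicer-deficient array 1 (0.195) or Dicer-deficient array 2 (0.207). Evx1 lost its call without each of the 5 arrays in turn (adjusted p from 0.0596 to 0.203). Srgn lost its call without wild-type array 1 or 2 or Dicer-deficient array 1 (adjusted p from 0.0527 to 0.0659). Olig2 and Snai1 lost their call without wild-type array 1 or 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.123 to 0.306). Msx2 lost its call without wild-type array 1 or 3 or Dicer-deficient array 1 or 2 (adjusted p from 0.114 to 0.293). Gsc and Map2 lost their call without wild-type array 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.0633 to 0.186). Kdr lost its call without wild-type array 2 or Dicer-deficient array 2 (adjusted p from 0.0532 to 0.0838). Lama1, Lrp2 and Msi1 lost their call without Dicer-deficient array 1 or 2 (adjusted p from 0.0574 to 0.114). Cdh2 lost its call without Dicer-deficient array 2 (adjusted p = 0.0645).

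Of 25 glycolysis genes, 15 fell and 2 rose (16 and 3 adjusted over the list alone), with a median log2 change of -0.45 (camera adjusted p = 8.29e-08; adjusted p = 0.449 with an estimated correlation). Slc2a3, a glucose transporter, went from 12.01 ± 0.00577 (SD, n = 3) to 10.54 ± 0.148 (SD, n = 2), 2.77-fold lower. The lactate exporter Slc16a3 was 3.48-fold lower, the lactate dehydrogenase subunit Ldhb 2.21-fold lower and Bnip3, a mitophagy receptor listed with them, 3.76-fold lower. Pfkm and Egln3 were the members that rose. Of 60 oxidative phosphorylation genes, 22 fell and 0 rose in limma (27 and 1 adjusted over the list alone), with a median of -0.24, but -0.15 without Dicer-deficient array 2 (camera adjusted p = 8.34e-08; adjusted p = 0.618 with an estimated correlation). Uqcrq of complex III fell by 0.99 and Ndufa6 of complex I by 0.78. Cholesterol synthesis genes had 9 of 20 lower and 2 higher (9 and 3 adjusted over the list alone; camera adjusted p = 0.00514; adjusted p = 0.618 with an estimated correlation). The cholesterol call was lost against random lists matched on level and span (adjusted p = 0.264) and with fry (adjusted p = 0.0537). Tm7sf2 was 1.78-fold lower, Stard4 1.91-fold lower and Fdft1, squalene synthase, 1.77-fold lower, while Ebp rose 1.87-fold and Hmgcs1 was also called higher. Pfkm lost its call without each of the 5 arrays in turn (adjusted p from 0.0535 to 0.237). Hmgcs1 lost its call without wild-type array 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.0512 to 0.105). Egln3 lost its call without Dicer-deficient array 1 or 2 (adjusted p from 0.0596 to 0.102).

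Of 30 genes of the unfolded protein and amino acid stress response, 12 fell and 2 rose (18 and 2 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 4.51e-06; adjusted p = 0.618 with an estimated correlation). Phgdh, the first enzyme of serine synthesis, was 2.25-fold lower and the stress-induced Nupr1 2.08-fold lower. The members that rose were Dnajb9 and Atf5. Immediate early and heat shock genes had 5 higher and 2 lower of 28 (5 and 2 adjusted over the list alone; camera adjusted p = 0.214, and 0.0224 without wild-type array 1), with Jun higher by 1.15. Klf6, Ccn1, Hsph1 and Dusp1 were also higher, and Ier3 and Hspe1 lower. Among 25 p53 targets, 4 rose and 5 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.843), with Eda2r higher by 1.15 and Pmaip1 by 1.01. Perp and Ei24 were also higher, and Tnfrsf10b, Zmat3, Mdm2, Trp53inp1 and Ccng1 lower. Among 28 apoptosis regulators, 6 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.911), with Tnfrsf10b at -0.87. For the p53 targets the median, -0.06, and camera pointed down and the mean, 0.03, up, and for the apoptosis regulators the median, -0.03, pointed down and the mean, 0.06, and camera up. The p53 median was -0.015 without wild-type array 2, -0.09 without wild-type array 3 and -0.01 without Dicer-deficient array 2, and the apoptosis median was -0.04 without wild-type array 1 and -0.005 without wild-type array 3. Ccng1 lost its call without each of the 5 arrays in turn (adjusted p from 0.0877 to 0.238). Trp53inp1 lost its call without each wild-type array in turn or Dicer-deficient array 2 (adjusted p from 0.0732 to 0.208). Atf5 lost its call without wild-type array 1 or 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.0662 to 0.151). Dusp1 lost its call without wild-type array 2 or 3 or Dicer-deficient array 1 or 2 (adjusted p from 0.0704 to 0.199). Mdm2 lost its call without wild-type array 2 or Dicer-deficient array 1 (adjusted p from 0.0575 to 0.0839). Dnajb9, Hspe1, Hsph1 and Perp lost their call without wild-type array 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.0505 to 0.249). Ccn1, Ei24, Ier3 and Zmat3 lost their call without Dicer-deficient array 1 or 2 (adjusted p from 0.0667 to 0.166).

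Of 49 DNA replication genes, 13 fell and 3 rose (15 and 3 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.000165; adjusted p = 0.628 with an estimated correlation). Gins2, a subunit of the replicative helicase, fell by 0.71, while Rrm1, of ribonucleotide reductase, rose by 0.55, and Ccne2 and Rfc3 were also called higher. Of 47 G2 and mitosis genes, 12 fell and 3 rose (16 and 5 adjusted over the list alone; camera adjusted p = 0.0062; adjusted p = 0.801 with an estimated correlation). That call was lost without wild-type array 1 (adjusted p = 0.0561) or Dicer-deficient array 1 (0.0585). The list's median was -0.08, but -0.145 without wild-type array 3 and -0.16 without Dicer-deficient array 2, and the wild-type arrays themselves had median deviations of 0.06, 0.02 and -0.11 over it. The G2 and mitosis call was also lost against random lists matched on level and span (adjusted p = 0.609) and with fry (adjusted p = 0.158). The securin gene Pttg1 was 2.43-fold lower, Pimreg 2.25-fold lower, the centromeric histone gene Cenpa 1.78-fold lower and Dlgap5 1.83-fold lower. Kif23, Mad2l1 and Anln were higher. Of 34 G1 and G1/S regulators, 8 rose and 3 fell (11 and 6 adjusted over the list alone, camera adjusted p = 0.183), the latter being Ccne1, Fbxo5 and Ccnd3. This list shares 8 genes with the reported targets of the miR-290, miR-302 and miR-17 families, that of cyclin D2 among them. Cyclin D2 (Ccnd2) rose 2.75-fold (adjusted p = 0.00312, and 0.0656 without Dicer-deficient array 2), whereas Ccnd1 had a change of 0.33 (adjusted p = 0.121) and Myc of 0.11 (adjusted p = 0.868). Ccnd1 had 0.51 without Dicer-deficient array 1 and 0.15 without array 2, and Myc had 0.60 and -0.38, with -0.04 without wild-type array 3. Replication-dependent histone genes had 4 lower and 0 higher of 22 in limma (4 and 0 adjusted over the list alone; camera adjusted p = 0.0092; adjusted p = 0.449 with an estimated correlation), with H2bc1 at a log2 change of -0.55 beside H2ac1, H2bc18 and H4c3. Their call was lost when dim genes were left out (adjusted p = 0.0611) and against random lists matched on level and span (adjusted p = 0.288). Fbxo5 and Rfc3 lost their call without each of the 5 arrays in turn (adjusted p from 0.0505 to 0.304). Ccnd3 lost its call without wild-type array 1 or 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.114 to 0.206). H2bc18 lost its call without wild-type array 1 or 3 or Dicer-deficient array 1 or 2 (adjusted p from 0.125 to 0.336). Anln, Ccne1, Ccne2, H2ac1 and H4c3 lost their call without Dicer-deficient array 1 or 2 (adjusted p from 0.0505 to 0.13).

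Of 41 genes listed for the actin cytoskeleton and matrix, annexins and keratins included, 20 rose and 2 fell (24 and 5 adjusted over the list alone). The median was 0.37 (camera adjusted p = 7.16e-07, and 0.449 with an estimated correlation). The actin genes Acta1 and Acta2 were not called, with changes of 0.01 and -0.06. Of the tropomyosin genes, whose products bind actin, Tpm1 and Tpm4 rose by 1.02 and 0.66, and Tpm2 had -0.08. Anxa2, another annexin, rose 5.76-fold from 7.58 ± 0.462 (SD, n = 3) to 10.11 ± 0.099 (SD, n = 2), and Ccn2, a secreted matrix protein, rose 2.87-fold. The members that fell were Fn1, fibronectin, and Actn1. Interferon response genes had 8 of 37 higher and 1 lower (8 and 1 adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.0124; adjusted p = 0.449 with an estimated correlation). Oas1a, a sensor of double-stranded RNA, rose 2.10-fold and the transcription factor Irf1 1.91-fold, while Stat2 was the member that fell. Fn1 lost its call without each wild-type array in turn or Dicer-deficient array 2 (adjusted p from 0.0829 to 0.202). Actn1 lost its call without wild-type array 1 or 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.0717 to 0.184).

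FGF/ERK feedback genes had 7 higher and 4 lower of 21 (7 and 4 adjusted over the list alone; camera adjusted p = 0.146, but 0.0296 without wild-type array 1 and 0.0419 without Dicer-deficient array 1). Spred1 rose 2.14-fold and the receptor Epha4 3.01-fold, and Ier3, Spry2, Epha2 and Spry1 were lower. Of 20 Wnt targets, 2 rose and 0 fell in limma (2 and 0 adjusted over the list alone; camera adjusted p = 0.122): the Wnt-inactivating enzyme Notum rose 4.13-fold and the Wnt inhibitor Apcdd1 3.41-fold. TGF-beta, Nodal and BMP genes had 9 higher and 5 lower of 32 (11 and 6 adjusted over the list alone; camera adjusted p = 0.341), the lower ones being Lefty2, Smad7, Tdgf1, Acvr1b and Smad1. Spry2 lost its call without each wild-type array in turn or Dicer-deficient array 1 (adjusted p from 0.103 to 0.246). Smad1 lost its call without each of the 5 arrays in turn (adjusted p from 0.0575 to 0.25). Epha2 lost its call without wild-type array 1 or 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.105 to 0.208). Acvr1b lost its call without wild-type array 1 or Dicer-deficient array 1 or 2 (adjusted p from 0.0507 to 0.136). Spry1 lost its call without wild-type array 2 or 3 or Dicer-deficient array 1 or 2 (adjusted p from 0.0732 to 0.197). Smad7 lost its call without wild-type array 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.0567 to 0.141). Ier3 lost its call without Dicer-deficient array 1 or 2 (adjusted p from 0.107 to 0.166).

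**Figure D2:**
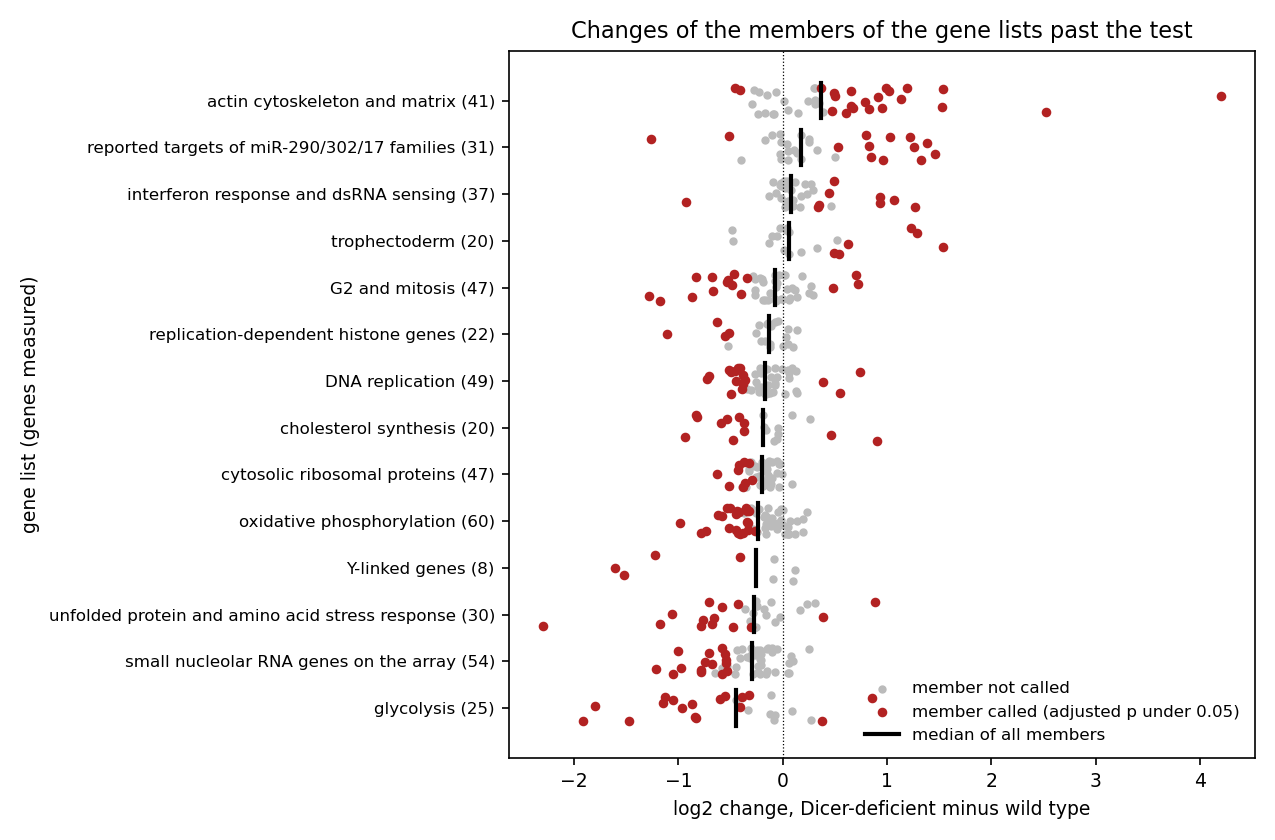
Log2 change (horizontal axis, Dicer-deficient minus wild type) of each measured member of the 14 gene lists past the camera test, with the number of members in parentheses, called members in red, others in grey, and the median as a black bar. Medians ran from -0.45 for glycolysis to 0.37 for the actin cytoskeleton and matrix.

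Chromatin and DNA methylation genes moved both ways. Polycomb genes had 4 higher and 6 lower of 33 (4 and 8 adjusted over the list alone; camera adjusted p = 0.911), with Pcgf5 and Aebp2 higher by 1.01 each, Jarid2 and Rbbp7 also higher, Pcgf2 at -0.86 and Ezh2 at -0.06 (adjusted p = 0.702), or -0.10 without Dicer-deficient array 1 and -0.02 without array 2. DNA methylation genes had 6 higher and 3 lower of 23 (8 and 6 adjusted over the list alone; camera adjusted p = 0.434). Gadd45b rose by 0.79, and Dnmt3l, Hells and Uhrf1 were lower. The de novo methyltransferase gene Dnmt3b rose by 0.54 (adjusted p = 0.0416), but its adjusted p lay between 0.0611 and 0.293 without each array in turn, and its log2 change was 0.31 without Dicer-deficient array 2. Dnmt3a had a change of -0.37 (adjusted p = 0.067). Germline genes that DNA methylation keeps silent had 3 higher and 4 lower of 35 (3 and 5 adjusted over the list alone; camera adjusted p = 0.843), Rhox9, Rpl10l and Rhox6 against Stag3, Mael, Tex15 and Stk31. The 2-cell-like genes had 1 higher and 1 lower of 19 (0 and 1 adjusted over the list alone; camera adjusted p = 0.911), Calcoco2 and Zfp365. For the latter the median, 0.02, and mean were positive and camera's direction negative, and for the germline genes the median, -0.02, and camera were negative and the mean positive. The germline median was 0.01 without wild-type array 3, -0.04 without wild-type array 1 and Dicer-deficient array 1 in turn, -0.01 without wild-type array 2 and 0.003 without Dicer-deficient array 2, and the 2-cell-like median was 0.01 without Dicer-deficient array 2. Dnmt3l lost its call without each wild-type array in turn or Dicer-deficient array 1 (adjusted p from 0.0661 to 0.278). Calcoco2 lost its call without each of the 5 arrays in turn (adjusted p from 0.0836 to 0.409). Hells, Mael, Rhox6, Stk31 and Uhrf1 lost their call without wild-type array 1 or 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.0507 to 0.249). Stag3 lost its call without wild-type array 1 or 2 or Dicer-deficient array 2 (adjusted p from 0.055 to 0.0865). Rbbp7 and Rpl10l lost their call without wild-type array 2 or 3 or Dicer-deficient array 1 or 2 (adjusted p from 0.0799 to 0.324). Jarid2 lost its call without wild-type array 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.0729 to 0.177). Rhox9 lost its call without Dicer-deficient array 1 (adjusted p = 0.0732). Tex15 lost its call without Dicer-deficient array 1 or 2 (adjusted p from 0.0546 to 0.0608).

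Of 37 imprinted genes, 6 rose and 7 fell (7 and 8 adjusted over the list alone; camera adjusted p = 0.779). Phlda2, an imprinted growth regulator, was 4.11-fold lower. Meg3 was 2.09-fold lower. Its neighbour Rian had a log2 change of -0.715, to a signal of 5.005 that was not shown to be above background. Both also belong to the list of 7 microRNA host and imprinted noncoding transcripts, of which 1, Mir302a, rose and these 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.911, with a median of 0.10, or 0.06 without Dicer-deficient array 2, against a mean and a camera direction below 0). Xist had signals of 3.92 and 3.86, below the lower quartile of every array, and a change of -0.06 (adjusted p = 0.741), or -0.03 without wild-type array 1, -0.11 without Dicer-deficient array 1 and -0.01 without array 2.

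Small nucleolar RNA genes had 15 of 54 lower and 0 higher in limma (17 and 0 adjusted over the list alone), with a median of -0.29, but -0.16 without wild-type array 1 (camera adjusted p = 5.6e-08; adjusted p = 0.726 with an estimated correlation). The largest fall held without each array was that of Snora21, with a log2 change of -0.97. The 3 wild-type arrays themselves differed over this list, with median deviations of 0.21, -0.01 and -0.21, and fry did not call it (adjusted p = 0.17). Cytosolic ribosomal protein genes had 9 of 47 lower and 0 higher in limma (15 and 0 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 5.96e-08; adjusted p = 0.618 with an estimated correlation). Rpl38 fell by 0.63. Genes of the same level and span had a typical median of -0.13, and 10.88% of random lists matched on both had a median as low as the ribosomal genes.

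Of 8 Y-linked genes, 4 fell and 0 rose in limma (4 and 0 adjusted over the list alone; camera adjusted p = 0.0107; adjusted p = 0.59 with an estimated correlation). Eif2s3y was 3.05-fold lower and Uty had a log2 change of -1.52, to a signal of 4.86 that was not shown to be above background. Zfy1 fell to a signal of 3.89, below the lower quartile of every array, so the size of its fall is not shown to rest on a signal above background (adjusted p = 0.00262, but 0.0887 and 0.0502 without Dicer-deficient array 1 and array 2), and Uba1y fell by 0.41 (adjusted p = 0.0293, and 0.176 when its probe sets were averaged). The call of Uba1y was also lost without wild-type array 2 (adjusted p = 0.1), wild-type array 3 (0.0527), Dicer-deficient array 1 (0.236) or Dicer-deficient array 2 (0.137). Without Dicer-deficient array 1 the list's adjusted p was 0.0876 and its median -0.17, against -0.25 with all arrays.

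Genes of chromosomes 14 and 11 were lower than those of other chromosomes. Of 392 genes above the median level on chromosome 14, 132 fell and 38 rose, with a median log2 change of -0.15 (camera adjusted p = 0.00118). On chromosome 11 the counts were 221 and 73 of 975, with a median of -0.09 (camera adjusted p = 0.00977, and 0.0623 without wild-type array 3). Over all genes with a chromosome the medians were -0.02 for chromosome 14 (adjusted p = 0.0407) and -0.03 for chromosome 11, which was then not called (0.0553). With an estimated correlation neither chromosome was called (adjusted p = 0.932 for both). On chromosome 14, 8 windows of 25 genes had a median below -0.2. Of these, 7 were neighbours, with medians from -0.55 to -0.22, that run from Samd4 to Sorbs3 in the gene order of the GRCm38.p6 assembly. Over the 175 genes of the run the median was -0.34, with 86 called lower and 7 higher, against -0.02 over the other 217 genes of the chromosome, among them the window left over, with a median of -0.32. Fdft1, Tnfrsf10b and Dlgap5, which fell, and Lats2, which rose, lie between the ends of this run. Among the genes named above under the rules for named genes, Pttg1, Pimreg, Uqcrq, Rpl38, Snora21, Upp1, Elobl, Slc16a3, Pcgf2 and Igfbp4, which fell, lie on chromosome 11. So do Notum, Calcoco2 and Irf1, which rose.

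**Figure D3:**
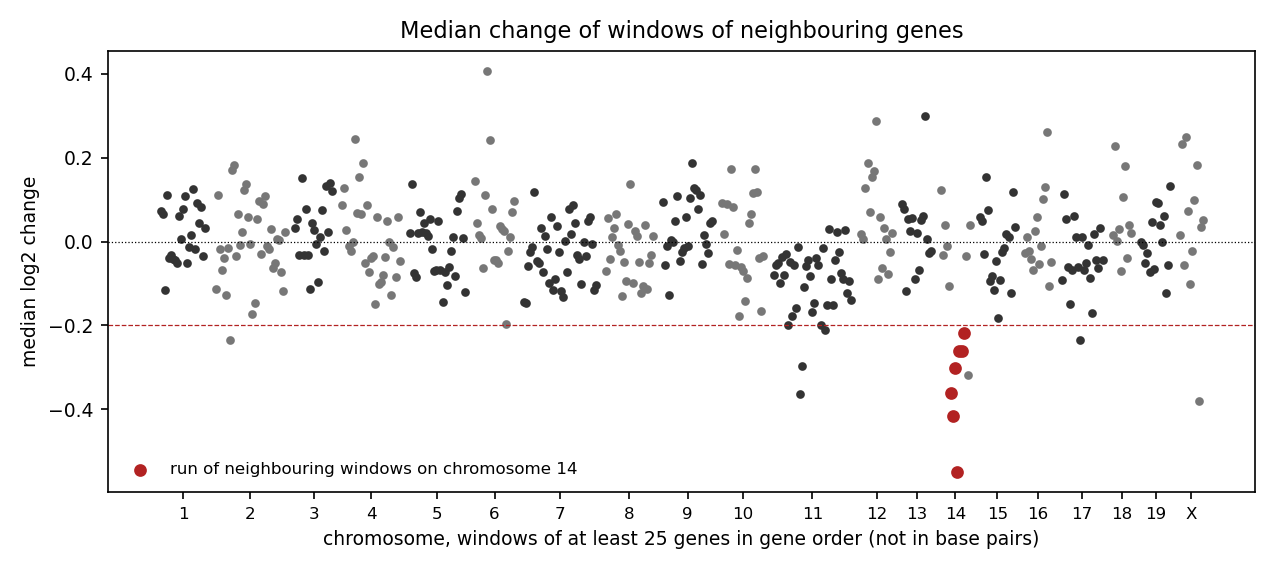
Median log2 change (vertical axis, Dicer-deficient minus wild type) of windows of at least 25 neighbouring genes above the median level, in gene order along chromosomes 1 to 19 and X (horizontal axis, each point a window, shades alternating by chromosome). The 7 red windows of chromosome 14 form the longest run below the dashed line at -0.2, with medians from -0.55 to -0.22.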

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

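Probe sets that the comparisons above left unnamed also held changes. Of 1621 probe sets whose annotation lists several genes, 21 were called higher and 96 lower in Dicer-deficient cells when all probe sets were tested together with limma, with log2 changes from -3.36 to 1.91. Of 12146 probe sets with no gene name, 127 were called higher and 291 lower, with log2 changes from -2.62 to 2.12. They are given because they lie outside the genes tested, and which transcripts they read was not examined. No technical or biological explanation was tested for them.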

How the results depend on the processing

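The matched random lists and the fit without genes of chromosomes 14 and Y were chosen after seeing the data; the other alternatives were set before. Of the 162 named genes, the lists and the chromosomes, none that was called changed direction under the alternatives run for it. All probe sets, the 2-fold minimum and treat gave gene counts only. Chromosomes were rerun only without 1 array, over all genes with a chromosome, with an estimated correlation and against matched random lists. Counts stayed within 1.5 times of 1690 higher and 1714 lower genes under the scaling, filter, trend, robust, weight and probe set alternatives. They fell to 307 and 151 with a change of at least 2-fold and to 655 and 489 with treat against 1.2-fold, both stricter by construction. Without 1 array there were 536 to 1396 genes higher and 434 to 1560 lower, with fewer arrays to estimate the spread; the lone Dicer-deficient array is then assumed to vary like the wild-type ones.

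With the replicate number as a block, 477 genes were called higher and 417 lower, and 885 of the 3404 calls were kept; the block leaves fewer residual degrees of freedom. Only 2 numbers are shared, and same-numbered arrays deviated together with correlations across genes of 0.0759 and 0.0249. The 2 Dicer-deficient arrays deviate as mirror images (correlation -1), so these values are not separate checks. Whether same-numbered arrays share more than a number stays open.

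Of the 14 gene lists called, 0 were called with an estimated correlation, which rests on 3 residual degrees of freedom, and 9 lists were called against matched random lists. Trophectoderm, G2 and mitosis, cholesterol synthesis, ribosomal protein and histone genes were no longer past the threshold against those lists, with adjusted p from 0.264 to 0.609. The cause was not tested. Without 1 array 12 to 15 lists were called. Of the 2 chromosomes called, 1 was called when all genes with a chromosome were used, 0 with an estimated correlation, 6 against matched random lists, and 1 to 3 without 1 array. Fry left out trophectoderm, DNA replication, G2 and mitosis, cholesterol synthesis and small nucleolar RNA genes (adjusted p from 0.0537 to 0.17) and called let-7 targets (0.0334), microRNA host transcripts (0.0164) and Wnt targets (0.0375), camera on ranks left out trophectoderm (0.121) and Y-linked genes (0.0892), and quantile normalization left out trophectoderm (0.0599). Among the named genes, calls lost numbered 54 with the block, 12 to 52 without 1 array and 0 to 2 under the alternatives of scaling, filter, trend, robust moderation, weights and probe set mean. Ago2 was called with dim genes left out, an intensity trend array weights or without wild-type array 3 (adjusted p from 0.0222 to 0.046), and Dnmt3a with median centring (0.0445) or dim genes left out (0.0369). Robust moderation was not run for the list test, which has no such option, and the seed-match alternatives were not run. Signal over background was not analysed here, so calls at low signal have no detection limit.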

Other observations

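The lists and tests here were all chosen after the values had been seen. Targets of NRF2, the transcription factor of the antioxidant response, were higher in Dicer-deficient cells: 14 of 27 rose and 1 fell, with a median log2 change of 0.55. No p is given for this list or the next, since this list was chosen after 2 of its members, Gpx2 and Ptgr1, were seen among the largest rises, and the next shares genes with a list already called. Cbr3, a carbonyl reductase, rose 4.56-fold. The glutathione transferase genes Gsta3 and Gsto1 rose 4.21-fold and 4.22-fold, Gclm of glutathione synthesis 2.22-fold, and the quinone reductase gene Nqo1 2.05-fold, besides Gpx2 and Ptgr1 among the largest rises. Hmox1, heme oxygenase, had a change of -0.18 (adjusted p = 0.375), and Taldo1 fell by 0.68. Of 29 targets of hypoxia-inducible factors, 13 fell and 3 rose, with a median of -0.45. Of these 29 genes, 11 also belong to the glycolysis list, and among the other 18, 6 fell and 2 rose. Vegfa, a vascular growth factor, was 2.61-fold lower. Against the direction of the list, Egln3, an oxygen-sensing hydroxylase, rose 1.81-fold, and Ak4 and Kdm3a were also higher. Gsto1 and Nqo1 lost their call without Dicer-deficient array 1 (adjusted p from 0.0512 to 0.0611). Egln3, Kdm3a and Taldo1 lost their call without Dicer-deficient array 1 or 2 (adjusted p from 0.0535 to 0.102).

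From the imprinted gene Dlk1 to the imprinted gene Dio3, both included, there are 47 measured genes, of which 4 were called lower and 0 higher by limma. These were Meg3, Rian, Dio3 and DQ267102, while Dlk1 had a change of 0.12 (adjusted p = 0.684). Over all genes tested 1714 of 19939 were called lower, about the same share, so the count alone does not set this stretch apart. The 40 microRNA genes of this stretch had a median change of -0.10; 30 lay below 0 and 0 were called. Larp7, within whose span the miR-302 cluster lies, rose 1.40-fold, and Mir367 of that cluster had a change of 0.29 (adjusted p = 0.128). The X-linked genes Bex1, Bex2, Bex3 and Bex4 all fell, with log2 changes of -2.02, -1.04, -0.59 and -2.59. Across 11143 genes above the median level, longer genes tended to be higher, with Spearman's rho = 0.178 between log2 change and gene span. The rho was 0.0566 to 0.241 within 5 classes of level, and genes are not independent replicates. The shortest of 10 classes of span had a median change of -0.03 and the longest 0.09. Bex3 and Dio3 lost their call without wild-type array 1 or 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.0692 to 0.199). DQ267102 and Larp7 lost their call without Dicer-deficient array 2 (adjusted p from 0.0563 to 0.0795).

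The first pattern is the run of 7 windows on chromosome 14, 175 genes with a median change of -0.34. Chance order is argued against by random orders of the genes: 0 of 1000 gave a run as long, and the longest had 2 windows. Level and gene span are argued against too, by runs sought on every other gene, and again on the rest. Both runs lay on chromosome 14, with 4 and 2 windows. A run of 2 windows also arose in the random orders of all genes, so the second search places the run less firmly. The 99 and 49 genes not searched within the 2 runs had medians of -0.227 and -0.298, while 10000 matched random lists went no lower than -0.133 and -0.21. Whether the Dicer-deficient cells hold fewer copies of the region than the wild-type cells stays open: the upper quartiles of these genes were 0.035 and -0.187, where a change shared by all neighbours needs both below 0. DNA was not measured, and an effect of Dicer loss on the region stays open as well.

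The second pattern is the lower signal of Y-linked genes. At most 0.311% of autosomal genes at the levels of Eif2s3y, Uty and Zfy1 fell as much. These genes were tested because they were called lower, so the small share decides nothing about them singly. The median over all 8 listed genes was -0.25, below that of all but 0.01% of random lists matched on level and span. A general shift of genes at the same level is thus argued against for the list as a whole. It stays open for Uba1y, whose fall 9.79% of such genes matched; the calls of Uba1y and Zfy1 were also lost without Dicer-deficient array 1 (adjusted p = 0.236 and 0.0887) or array 2 (0.137 and 0.0502), and that of Uba1y without wild-type array 2 (0.1) or 3 (0.0527). A Y chromosome missing from the Dicer-deficient cells, or from many of them, stays open: of 4 Y-linked genes with a wild-type signal above the median of all probe sets, 1 was not called lower, Sry, at 5.81 with a change of 0.10 (adjusted p = 0.687), and whether ES cells express it was not examined. Kdm5d, with a wild-type signal of 4.38, had a change of -0.09 (adjusted p = 0.775), too dim to decide, and DNA was not measured.

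The third pattern is the higher signal of T cell receptor transcripts, Cd3g (2.97), Cd3d (2.21), Cd3e (1.25) and Cd4 (1.13, log2 changes). T cells in the cultures are argued against, because 25 other T cell transcripts had a median change of 0.00667, an upper quartile of 0.08, and 1 called higher, Tmsb4x, which many cell types express. Abundant ones such as Ptprc and Coro1a had changes of -0.04 and -0.34 (adjusted p = 0.844 and 0.167), and Lat and Laptm5 fell by 0.66 and 0.54, the latter no longer called without wild-type array 1 or 2 or Dicer-deficient array 1 or 2 (adjusted p from 0.0981 to 0.284). A shift shared with the genes around the 3 neighbouring Cd3 genes is argued against as well, since 0 of the 10 nearest measured genes were called higher, with changes from -0.38 to 0.48. What raised these transcripts stays open, an effect of Dicer loss on them included.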
